A study of Mus musculus with 3 samples.

How the data were processed

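Single-nucleus RNA was measured in the deep cerebellar nuclei (DCN), the output nuclei of the cerebellum, of male C57Bl/6N mice aged 6 to 8 weeks. There were 3 libraries, 1 per group. The home cage group is HC. The fear conditioned group is FC, in which 5 tones (30 s, 2800 Hz, 79 dB) were each paired with a foot shock (2 s, 0.5 mA). The group after auditory memory retrieval is TN, in which conditioned mice heard 2 or 3 tones in another chamber 24 h later. Tissue was collected 30 minutes after conditioning or retrieval, from slices of 300 µm. Whether animals were pooled into a library is not stated. The time of day at which each library was collected, the handling of the home cage mice, the counting of intronic reads and the release of the annotation behind the counts are not given in the sources used here.

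The deposited values are raw UMI counts per gene and barcode, 1 matrix per library, with 32285 genes. The submitters' processing notes credit them to Cell Ranger 7.1.10 and the mm10 genome. Every value checked was a whole number. The smallest total of a barcode was 500 UMIs. By Ensembl identifier, 32158 of the genes were matched to GENCODE release M21 on build GRCm38, which gave the coordinates. The 78 genes that share a symbol were kept apart by identifier. Spatial data of the same series were not analysed here.

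The HC, FC and TN libraries held 7410, 10494 and 7577 barcodes, with 13982668, 16661487 and 13558624 UMIs. Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were used, which left 6249, 8152 and 6257. Fewer than 500 genes were seen in 1045, 2091 and 1181 barcodes, and more than 5% mitochondrial UMIs in 141, 308 and 169. Each nucleus was scored for doublets by its 50 nearest neighbours among observed and simulated profiles (2 simulated per nucleus, 30 principal components). In each library the highest scores were removed, at 0.8% per 1000 nuclei, which took out 312, 532 and 313 nuclei and left 5937, 7620 and 5944. No correction for free RNA was applied. The levels of each cell type's markers in the other types were reported in its place.

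Counts were scaled per nucleus and log transformed. From 2000 variable genes, 40 principal components were taken, a shared nearest neighbour graph was built (20 neighbours), and Leiden clustering at resolution 1.0 was run over the 3 libraries without integration. This gave 22 clusters. Names came from 21 lists of marker genes written before the data were examined, as were the gene lists, the comparisons, the filters and all alternatives except those said below to be later. The scoring rule for names was set after the data were seen. A marker counted when its CPM in the cluster was above that in the other nuclei by a log2 fold of 1, with 10 CPM added and detection in at least 10% of nuclei. The list with the most such markers gave the name, if it had at least 3, was not tied and was not outnumbered among the top 10 genes. A cluster stayed unnamed if its mean doublet score was above 0.8, if more than 2 of its top 10 genes encoded ribosomal proteins or haemoglobin, or if under 50% of its nuclei kept the name at resolution 2.0. By these rules 6 clusters stayed unnamed. Names are by resemblance to markers alone, so each class is to be read as, for example, granule-like. Clusters 1 and 4 form the oligodendrocyte class, and clusters 3 and 8 the astrocyte class.

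UMIs were summed over the nuclei of a class in each library and divided by the class total and scaled to a fixed total to give CPM, the usual unit of relative counts. The comparisons were FC against HC, TN against HC and TN against FC, in classes with at least 50 nuclei in each library. With 1 library per group there was no test across samples, no p-value and no check between replicates. A gene's log2 ratio is that of its CPM, with a 95% exact conditional binomial (Clopper-Pearson) interval. CPM have exact Poisson intervals and shares exact binomial intervals. All intervals cover counting error only, not differences between animals, dissections or library preparations. FC over HC and TN over HC share the HC library and are not independent.

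The 21 gene lists covered rapid immediate early, later activity-induced, glucocorticoid-induced, circadian clock, heat shock, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal protein, myelin, cholesterol synthesis, astrocyte reactivity and metabolism, and inflammatory response genes, and ionotropic and metabotropic glutamate receptors, GABA and glycine receptors, voltage-gated sodium, potassium and HCN, and calcium channels, vesicle release genes, synaptic plasticity kinases and scaffolds, and monoamine and acetylcholine receptors. A member was measured with at least 20 UMIs over both libraries in the class. The list's value is the median log2 ratio of its measured members, with 0.5 counts added to each gene and 1 to each total. Its counting interval comes from 2000 Poisson draws. With at least 5 measured members, the median was placed among 10000 random lists of the same size, matched gene by gene in 20 bins of expression. This percentile describes these libraries, and members of a list are not independent. A list of endoplasmic reticulum chaperones and unfolded protein response genes was written after the data were seen. Nuclei with a UMI of Fos, Fosb, Junb, Egr1, Arc, Npas4 or Nr4a1 were counted with all UMIs and after thinning each nucleus to 1000 UMIs, which leaves out nuclei with fewer.

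Named genes were chosen by rule. In FC against HC and in TN against HC, these are the 3 genes higher and the 3 genes lower whose interval lay farthest from 0 in each of the DCN glutamatergic, DCN inhibitory, granule, astrocyte and oligodendrocyte classes. They needed at least 50 UMIs over both libraries, at least 20 CPM in the higher library and a CPM of at least 20% of that in the highest class, and could not be mitochondrially encoded. In TN against FC, 1 gene each way was taken. Up to 2 members each way were named for each list whose median lay outside the central 95% of random lists, and a part of these is given. Sgk1, Fkbp5, Nfkbia, Plin4, Per3, Nr1d2, Tef, Npas4, Fos, Arc, Gadd45g, Hspa5, Hsp90b1, Calr and Ttr are given in classes where this rule does not name them, and were chosen there after their values were seen.

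The intervals and percentiles were tested on simulated data, Poisson counts drawn from the pooled profile of each pair of libraries with known ratios added. In FC over HC and in TN over HC, the intervals held the true ratio for 95.8% and 95.7% of 8378 and 8247 genes in DCN glutamatergic nuclei, and for 96.1% and 95.7% of 8923 and 9077 genes in oligodendrocytes. A fold of 2 left 0 outside the interval for 90.5% and 95.1% of genes in DCN glutamatergic nuclei, and for 90.1% and 93.1% in oligodendrocytes. Lists without a shift lay outside the central 95% of random lists in 3%, 6%, 3% and 4.5% of draws, in the same order. These draws hold counting error alone and lists of unrelated genes, so they check the arithmetic rather than the spread of real data. Observed ratios were wider. In oligodendrocytes, FC over HC, the median absolute log2 ratio around its median was 0.177, against 0.127 in Poisson draws.

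The alternatives were centring on the median gene, edgeR TMM factors, totals without mitochondrially encoded genes and the 50 most abundant genes, the mean over nuclei of each nucleus's CPM, thinning to 1000 UMIs, list members with at least 10 or 50 UMIs, 2 counts added, no filter on nuclei, at least 1000 genes per nucleus, no doublets removed, 1.6% per 1000 nuclei removed, Leiden resolutions 0.5 and 2.0, and thinning to 500 or 2000 UMIs for the immediate early nuclei. Each oligodendrocyte and astrocyte cluster alone was added after the data were seen. Across the 5 classes named above, the median log2 ratio of all genes stayed under 0.1 from 0. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16, used for TMM factors alone.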

Results

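Nuclei of the mouse deep cerebellar nuclei were profiled by droplet RNA sequencing after auditory fear conditioning, after retrieval of the tone memory 24 h later, and in mice left in the home cage. There was 1 library per group, so no value below has a spread between replicates. Quality filters left 5937 nuclei in the home cage (HC) library, 7620 in the fear conditioned (FC) library and 5944 in the tone retrieval (TN) library, 19501 in all. Their median depths were 1441, 1317.5 and 1489 UMIs. Before filtering, the libraries held 13982668, 16661487 and 13558624 UMIs. Values in brackets are 95% counting intervals.

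The nuclei included glutamatergic neurons of the DCN (marked by Slc17a6 and Spp1), inhibitory DCN neurons (Gad1, Sox14), granule cells (Gabra6), astrocytes and oligodendrocytes. Oligodendrocytes made up 26.6% (25.5 to 27.7) of nuclei in HC, 34.5% (33.4 to 35.6) in FC and 44.1% (42.8 to 45.4) in TN. Granule cells made up 29.9% (28.7 to 31.1), 20.2% (19.3 to 21.1) and 11.5% (10.7 to 12.3). Astrocytes made up 16.1% (15.2 to 17.05), 20.5% (19.6 to 21.5) and 20.2% (19.2 to 21.2). DCN glutamatergic neurons were 4.43% (3.92 to 4.98), 5.22% (4.73 to 5.75) and 4.91% (4.38 to 5.49), which is 263, 398 and 292 nuclei. DCN inhibitory neurons were 5.19% (4.64 to 5.78), 6.22% (5.69 to 6.79) and 6.41% (5.80 to 7.06), or 308, 474 and 381 nuclei. Bergmann glia, which lie in the cortex rather than the nuclei, were 1.53% of HC but 0.499% of FC and 0.454% of TN nuclei, and ependymal cells 0.842%, 0.262% and 0.320%. Shares of nuclei depend on where the slices were dissected and on which nuclei passed the filters: with at least 1000 genes per nucleus, DCN glutamatergic neurons made up 15.6%, 24.5% and 18.4%. With that filter FC no longer lay above HC for astrocytes, at 6.83% against 10.3%, or for oligodendrocytes, at 12.1% against 12.4%.

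Median depth per nucleus in HC, FC and TN was 6197, 4622.5 and 5272.5 UMIs for DCN glutamatergic neurons, 3440, 2561.5 and 3066 for DCN inhibitory neurons, 1033, 993 and 1014 for granule cells, 1614, 1384 and 1524 for astrocytes, and 1420, 1258.5 and 1375 for oligodendrocytes. Oligodendrocytes were formed by clusters 1 and 4 and astrocytes by clusters 3 and 8. Of the clusters without a name, cluster 7, which had as many markers of molecular layer interneurons as of DCN inhibitory neurons, held 3.27%, 2.76% and 3.398% of the nuclei. The glycine transporter gene Slc6a5 gave 76, 68 and 78 UMIs in it, against 0, 1 and 7 in the class named DCN inhibitory, which had 4 of the 10 markers of its list. Cluster 9 held 2.98%, 2.17% and 1.45%, cluster 16 held 0.219%, 0.656% and 0.488%, and cluster 22 held 0.404%, 0.131% and 0.118%, all with high doublet scores. Cluster 11, which had 6 of 12 Purkinje cell markers and 5 of DCN inhibitory neurons, held 3.05%, 0.682% and 0.656%, and 6.25% of its nuclei kept the Purkinje name at the finest resolution. Cluster 18, led by ribosomal protein and haemoglobin genes, held 0.387%, 0.223% and 0.505%.

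**Figure D1:**
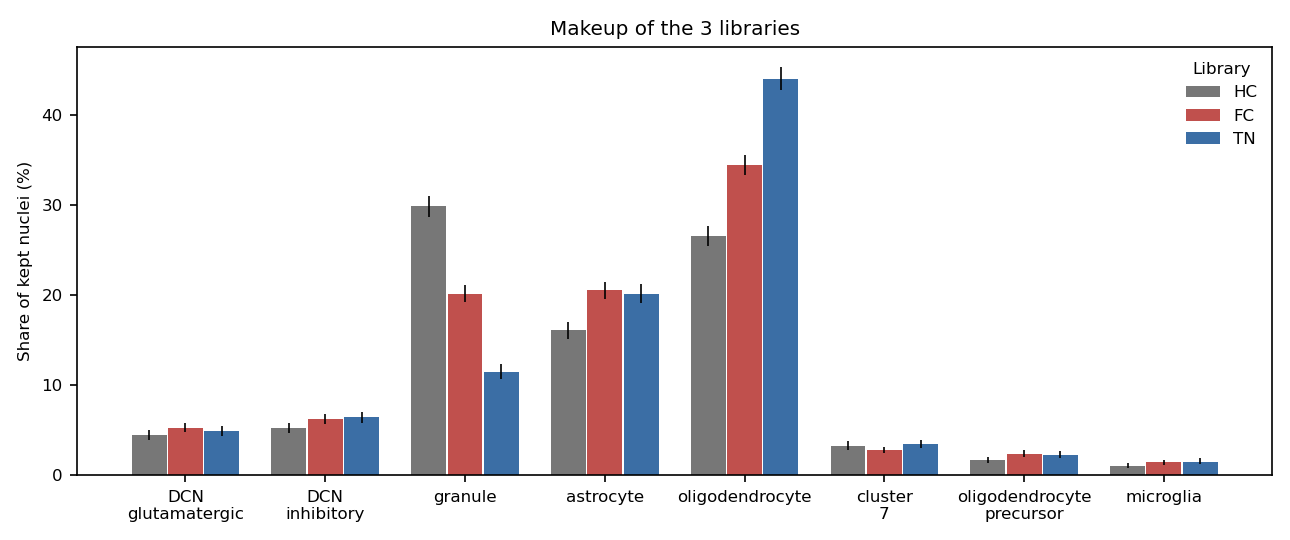
Share of kept nuclei (%) in each cell class for the HC (grey), FC (red) and TN (blue) libraries, with exact binomial 95% intervals as bars. Granule cells go from 29.9% in HC to 11.5% in TN, and oligodendrocytes from 26.6% to 44.1%.

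Fear conditioning was compared with the home cage to ask which genes differ in cerebellar output nuclei 30 minutes after learning. Glucocorticoid-induced genes were higher in the FC library, in glia, granule cells and DCN inhibitory neurons. In oligodendrocytes 15 of 17 measured members were higher, with a median log2 ratio of 0.64 (0.52 to 0.73). Sgk1, a kinase that answers to corticosterone, went from 598 CPM in HC to 1054 CPM in FC, 1.76-fold (1.66 to 1.87). Pdk4, which switches cells from glucose to fat use, went from 15.9 to 38.5 CPM, and Nfkbia, which holds back NF-kB, from 49.0 to 115 CPM.

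The gene for Sgk1 (ENSMUSG00000019970) lies on chromosome 10 of GRCm38 at 21882184 to 21999903, and Pdk4 (ENSMUSG00000019577) on chromosome 6 at 5483351 to 5496309. The log2 ratio in oligodendrocytes was 0.82 (0.73 to 0.90) for Sgk1, 1.27 (0.76 to 1.82) for Pdk4, 1.24 (0.94 to 1.54) for Nfkbia and 1.89 (0.85 to 3.10) for the sulfotransferase Sult1a1. Fkbp5, which dampens the glucocorticoid receptor, stood at 74.1 CPM in HC and 91.6 CPM in FC, a log2 ratio of 0.31 (0.04 to 0.57). Tsc22d3, another target of the receptor, was not higher, at 82.1 and 72.6 CPM. The list's median was 0.38 (0.29 to 0.52) in astrocytes with 16 of 18 higher, 0.60 (0.33 to 0.76) in granule cells with 12 of 13, and 0.30 (0.03 to 0.54) in DCN inhibitory neurons with 10 of 12, all outside the central 95% of random lists. The astrocyte median was 0.19 with at least 1000 genes per nucleus. Markers of other cell types were also higher in these nuclei: oligodendrocyte markers were at 0.69 (0.62 to 0.75) in granule and 0.58 (0.51 to 0.65) in astrocyte nuclei, microglia markers at 1.34 (0.99 to 1.70) in granule, 0.83 (0.50 to 1.17) in astrocyte and 1.0047 (0.73 to 1.29) in oligodendrocyte nuclei, and astrocyte markers at 0.88 (0.57 to 1.19) in DCN inhibitory nuclei. In DCN glutamatergic neurons the list was at 0.07 (-0.08 to 0.45), at the percentile 76.3 of random lists. Astrocyte Sgk1 had a ratio of 1.21 (0.74 to 1.71) and Fkbp5 0.71 (0.23 to 1.20), while Mertk, a receptor for engulfing debris, was lower at -0.53 (-0.74 to -0.32). In nuclei with at least 1000 genes the ratio of FC over HC changed sign for Fkbp5 in astrocytes (-0.01) and Sgk1 in granule cells (-0.14 in place of 0.75), and for the list in oligodendrocyte precursors (-0.42 in place of 0.53). That filter leaves 172 and 109 astrocytes, 120 and 59 granule cells, and 24 and 28 precursors in HC and FC.

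**Figure D2:**
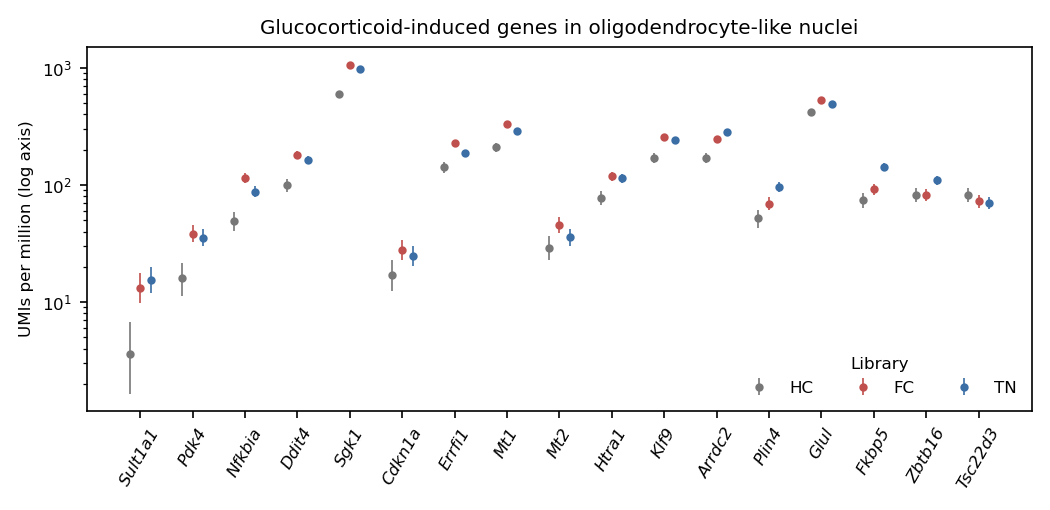
CPM (log axis) of 17 glucocorticoid-induced genes in oligodendrocytes of the HC (grey), FC (red) and TN (blue) libraries, points with exact Poisson 95% intervals. Sgk1 stands at 598 CPM in HC and above it in both other libraries, while Tsc22d3 does not.

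Immediate early genes, which neurons switch on within minutes of strong activity, were not higher in DCN glutamatergic neurons of the FC library. The list's median there was -0.03 (-0.34 to 0.29) over 12 members, of which 6 were higher. Fos had 13 UMIs in HC and 6 in FC, a log2 ratio of -1.28 (-2.96 to 0.21). Npas4, a transcription factor that answers to calcium entry, had 15 and 2 UMIs, a ratio of -3.07 (-6.24 to -0.97), and Arc had 23 and 26 UMIs, a ratio of 0.01 (-0.86 to 0.89). Of DCN glutamatergic nuclei, 18.3% (13.8 to 23.5) in HC, 14.8% (11.5 to 18.7) in FC and 19.9% (15.4 to 24.9) in TN had a UMI of Fos, Fosb, Junb, Egr1, Arc, Npas4 or Nr4a1. After thinning to 1000 UMIs these shares were 4.58% (2.39 to 7.86), 3.77% (2.12 to 6.14) and 3.77% (1.90 to 6.64), with 1, 0 and 0 nuclei left out. Glia were set beside them: oligodendrocytes had thinned shares of 2.97% (2.16 to 3.98), 2.70% (2.06 to 3.46) and 1.97% (1.44 to 2.61) and unthinned shares of 5.64%, 3.69% and 2.82% at median depths of 1420, 1258.5 and 1375 UMIs. Astrocytes had thinned shares of 0.447% (0.122 to 1.14), 1.38% (0.836 to 2.15) and 0.803% (0.368 to 1.52) and unthinned shares of 1.36%, 1.79% and 1.33%. The thinned intervals of DCN glutamatergic neurons overlap those of oligodendrocytes in each library. DCN inhibitory neurons had thinned shares of 0.654% (0.0793 to 2.34), 1.06% (0.346 to 2.47) and 2.63% (1.27 to 4.79), below oligodendrocytes in HC and FC, and granule cells 7.43%, 7.19% and 7.52%. The DCN inhibitory shares rest on 2, 5 and 10 nuclei. They were 5.19%, 1.90% and 4.99% unthinned and 3.79%, 1.39% and 4.14% when thinned to 2000 UMIs. FC was lowest in both of these, so the order of the libraries depends on the setting. No difference between the libraries in the share of DCN glutamatergic nuclei was detectable at this depth. In granule cells the list's median was 0.07 (-0.14 to 0.27), with Npas4 at 22 and 6 UMIs, a ratio of -1.60 (-3.19 to -0.26). Astrocytes had a median of 0.33 (-0.02 to 0.47), outside the random lists, with Jun at 0.64 (0.05 to 1.25) and Btg2 at -1.31 (-2.16 to -0.50). That median was -0.05 in astrocytes with at least 1000 genes. Later activity-induced genes had a median of 0.19 (-0.11 to 0.40) in DCN glutamatergic neurons, -0.31 (-0.46 to 0.11) in astrocytes, where Plk2 was at -0.57 (-1.14 to -0.01), and 0.47 (0.26 to 0.71) in oligodendrocytes, where the transcriptional repressor Crem was at 0.99 (0.09 to 1.98).

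Genes of energy use were also higher in the FC library. Mitochondrially encoded genes had a median of 1.19 (1.10 to 1.35) in DCN glutamatergic neurons, with 12 of 12 higher and mt-Co2, a subunit of cytochrome oxidase, at 1.45 (1.28 to 1.63). The medians were 1.07, 0.95, 0.59 and 0.61 in DCN inhibitory neurons, granule cells, astrocytes and oligodendrocytes. These transcripts lie outside the nucleus, so they also measure the cytoplasm carried into droplets, and the median mitochondrial share of a nucleus was 0.123% in HC, 0.235% in FC and 0.19% in TN. Nuclear oxidative phosphorylation genes had medians of 0.27 (0.20 to 0.35) in oligodendrocytes with 30 of 31 higher, 0.31 (0.21 to 0.40) in astrocytes with 28 of 31, and 0.17 (0.09 to 0.25) in granule cells with 23 of 31, but 0.01 (-0.04 to 0.14) in DCN glutamatergic neurons. Whether cytoplasm carried into droplets also raised these genes or the ribosomal protein genes below was not tested. Cox5a was at 0.64 (0.41 to 0.88) in oligodendrocytes and Cox6a1 at 0.82 (0.40 to 1.26) in astrocytes. Ribosomal protein genes had medians of 0.29 (0.17 to 0.35) in astrocytes, 0.17 (0.06 to 0.26) in DCN glutamatergic neurons and 0.10 (0.02 to 0.17) in granule cells, the last becoming -0.07 with at least 1000 genes per nucleus. Heat shock genes, which encode protein-folding helpers, had medians of 0.31 (0.16 to 0.39) in oligodendrocytes with Hsph1 at 0.63 (0.32 to 0.94), 0.22 (0.06 to 0.29) in granule cells and 0.19 (0.07 to 0.32) in DCN glutamatergic neurons with Dnaja1 at 0.54 (0.29 to 0.80).

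Cholesterol synthesis genes were higher in DCN glutamatergic neurons and granule cells of the FC library and lower in its oligodendrocytes. The medians were 0.21 (0.01 to 0.33) in DCN glutamatergic neurons, 0.18 (-0.06 to 0.31) in granule cells, 0.15 (-0.02 to 0.27, within the random lists) in DCN inhibitory neurons and -0.14 (-0.24 to -0.03) in oligodendrocytes, where 5 of 20 were higher, Hmgcs1, the first committed enzyme of the pathway, was at -0.42 (-0.65 to -0.19), and the median was 0.02 with at least 1000 genes per nucleus. Fdps (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), which makes farnesyl diphosphate, went from 18.7 to 42.4 CPM in DCN glutamatergic neurons, 2.27-fold, with a log2 ratio of 1.18 (0.59 to 1.81). Oligodendrocyte markers in those nuclei stood at 734 CPM in HC and 905 CPM in FC. Clock genes were at 0.15 (0.03 to 0.26) in astrocytes, within the random lists, and in oligodendrocytes, outside them, at 0.26 (0.03 to 0.43), with Ciart at 1.32 (0.47 to 2.25) and Per3 at 0.60 (0.33 to 0.88), which was -0.41 with at least 1000 genes.

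Of the channel and synapse lists in DCN glutamatergic neurons, most had medians within the random lists: -0.01 (-0.14 to 0.12) for ionotropic glutamate receptors, 0.02 (-0.15 to 0.18) for GABA and glycine receptors, -0.08 (-0.17 to 0.05) for synaptic plasticity kinases and scaffolds, -0.24 (-0.38 to 0.29) for monoamine and acetylcholine receptors, and -0.14 (-0.23 to 0.01) for calcium channels, with 2 of 13 higher. Metabotropic glutamate receptors lay outside them, at -0.28 (-0.46 to 0.05) with 1 of 5 higher and Grm4 at -0.79 (-2.03 to 0.38). In granule cells, calcium channels had a median of -0.27 (-0.44 to -0.14) with 1 of 12 higher and Cacna1g, a low-voltage channel, at -0.98 (-1.64 to -0.36). Purkinje markers in granule nuclei also differed, at 230 CPM in HC and 125 CPM in FC, as did molecular layer interneuron markers, at 436 and 322 CPM. Vesicle release genes had medians of -0.11 (-0.27 to -0.02) in DCN inhibitory neurons, where the release factor Unc13c was at -1.02 (-1.66 to -0.40), -0.13 (-0.19 to -0.03) in granule cells and 0.24 (-0.00 to 0.32) in oligodendrocytes. Granule markers in DCN inhibitory nuclei stood at 210 CPM in HC and 172 CPM in FC. Ionotropic glutamate receptors were lower in FC in astrocytes and oligodendrocytes, with medians of -0.21 (-0.39 to -0.03) in astrocytes (Grin2b -0.72, -1.12 to -0.32) and -0.34 (-0.66 to -0.15) in oligodendrocytes (Grik1 -1.06, -1.70 to -0.44). Purkinje markers were lower there too, at 166 CPM in HC and 134 CPM in FC in astrocyte nuclei and at 85.7 and 40.4 CPM in oligodendrocyte nuclei. Other neuronal markers in oligodendrocyte nuclei were higher, those of molecular layer interneurons at 394 CPM in HC and 512 CPM in FC and those of granule cells at 254 and 295 CPM. Potassium and HCN channels had a median of -0.20 (-0.31 to 0.17) in astrocytes, which was 0.07 over members with at least 50 UMIs and 0.31 with at least 1000 genes per nucleus. Sodium channels had a median of 0.34 (-0.03 to 0.71) in oligodendrocytes with 5 of 5 higher, beside molecular layer interneuron markers there at 0.38 (0.27 to 0.49). Astrocyte reactivity and metabolism genes had a median of 0.14 (0.05 to 0.19) in astrocytes, with the intermediate filament Gfap at 0.55 (0.24 to 0.87). The inflammatory response list, with 4 of 4 measured members higher in astrocytes and a median of 0.71 (0.19 to 1.01), had too few for a percentile.

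By the ranking over single genes, the DCN glutamatergic neurons of FC had more of Zfp560 (1.80, 0.87 to 2.85), Adck2 (1.49, 0.59 to 2.47) and Fdps, and less of Cfap20 (-1.39, -2.06 to -0.75), Lpcat4 (-1.18, -1.62 to -0.75), an enzyme of membrane lipids, and Snrpf (-1.23, -1.79 to -0.69), a core splicing protein. The DCN inhibitory neurons had more of Ten1 (1.35), Gstm5 (1.09) and the reelin receptor gene Lrp8 (0.65, 0.41 to 0.89, from 197 to 309 CPM), and less of Uchl4 (-1.32), Snrpf (-1.18) and Gpr162 (-0.92). Granule cells had more of Mal (0.98), Stmn4 (1.03) and Klk6 (1.20), which oligodendrocytes express, and less of Crtc2 (-1.52), a coactivator of CREB, A230051N06Rik (-1.42) and Paqr9 (-1.30). With at least 1000 genes per nucleus, Klk6 was at -0.59 and Stmn4 at -0.23 in granule cells. Astrocytes had more of E230001N04Rik (1.25), Tbc1d1 (1.23) and Vhl (1.46), and less of 4930480K15Rik (-1.31), the fatty acid binding protein gene Fabp7 (-1.33) and Slc25a44 (-1.46). Fabp7 is also on the marker list of Bergmann glia, which made up 1.53% of HC, 0.499% of FC and 0.454% of TN nuclei. Whether class mix or free RNA lowers it was not tested. Oligodendrocytes had more of E230001N04Rik (1.52, 1.13 to 1.92), Itgad (1.10) and Pdk4, and less of Snrpf (-1.16, -1.49 to -0.83, from 76.9 to 34.4 CPM), Gm29237 (-0.87) and Gm42695 (-1.17). E230001N04Rik (chromosome 17, 28522720 to 28525398) lies 5192 bases from Fkbp5 on the other strand. Snrpf (ENSMUSG00000020018) lies on chromosome 10 at 93583029 to 93589706. It was lower than in HC in each of the 5 classes, in both FC and TN, with every interval below 0. The smallest differences were -0.85 in granule cells of FC and -0.85 in DCN inhibitory neurons of TN. Its difference thus sets the HC library apart rather than a class, and its cause cannot be told with 1 library per group.

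Transcripts of other cell types within a class differed between the libraries. Myelin genes had a median of -0.03 (-0.11 to -0.02) in oligodendrocytes, their source, but 0.60 (0.47 to 0.81) in granule cells and 0.53 (0.29 to 0.65) in astrocytes. Oligodendrocyte markers in granule nuclei stood at 1774 CPM in HC, 2858 in FC and 2665 in TN. Per nucleus these were 2.01 UMIs in HC and 3.10 in FC, while DCN inhibitory neurons had 5.31 and 3.80, so the libraries differed in opposite directions. In oligodendrocyte nuclei, astrocyte markers stood at 230, 344 and 248 CPM. Ttr, a choroid plexus transcript, gave 0.266 UMIs per DCN glutamatergic nucleus in HC and at most 0.0151 in each class of FC and TN that was compared. Astrocyte genes in oligodendrocytes (median 0.51, 0.27 to 0.59, with Gja1 at 0.78) and in DCN inhibitory neurons (0.43, 0.21 to 0.67) are open to free RNA and are not assigned to those cells.

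**Figure D3:**
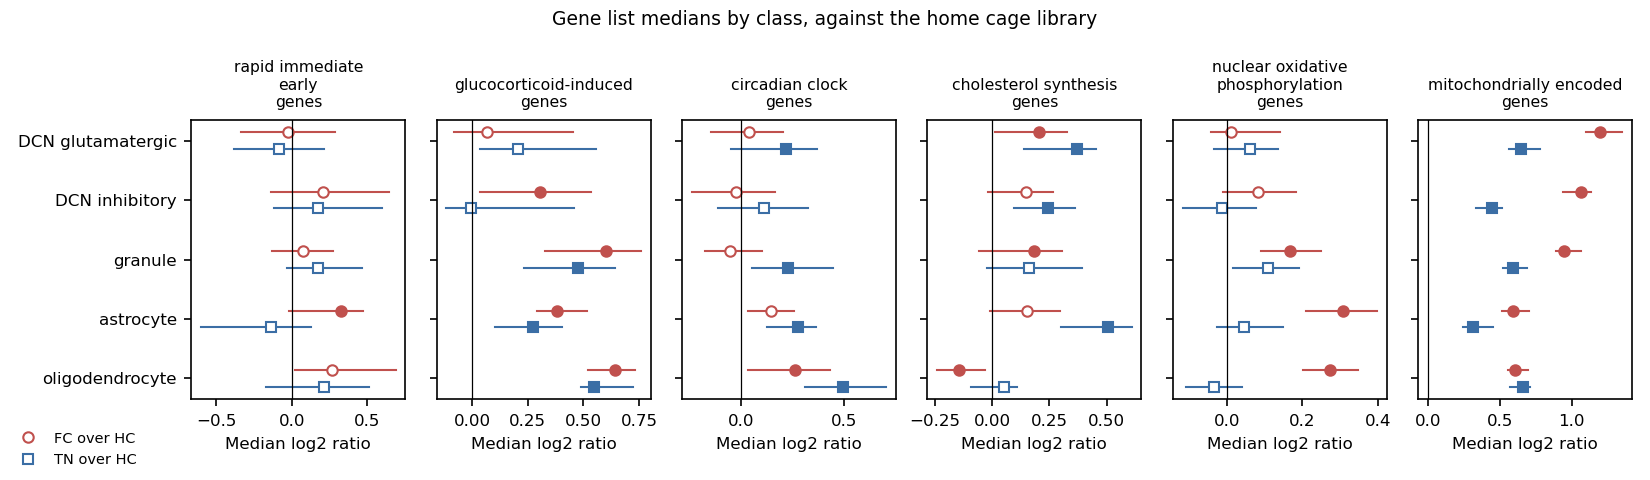
Median log2 ratio over the home cage library for 6 gene lists in 5 cell classes, FC as red circles and TN as blue squares, with counting 95% intervals as lines. Filled symbols lie outside the central 95% of matched random lists, as do the glucocorticoid-induced genes in oligodendrocytes at 0.64 in FC and 0.55 in TN.

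Tone retrieval was compared with the home cage to ask which genes differ after recall of the memory. Glucocorticoid-induced genes were again higher in oligodendrocytes, with 16 of 17 members higher and a median of 0.55 (0.49 to 0.72). Fkbp5 went from 74.1 CPM in HC to 142 CPM in TN, and Sgk1 from 598 to 971 CPM. Microglia markers in these nuclei stood at 56.2 CPM in HC, 113 in FC and 98.6 in TN. Clock genes were higher in most classes: Ciart, a repressor within the clock, went from 5.98 to 28.3 CPM in oligodendrocytes, and Per3 from 64.5 to 168 CPM. Genes of cholesterol synthesis were higher in astrocytes and in both DCN neuron classes, and the endoplasmic reticulum chaperone gene Hspa5 was lower in granule cells, at 107 CPM against 232 CPM.

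The clock list's median was 0.49 (0.31 to 0.71) in oligodendrocytes with 14 of 17 higher, 0.28 (0.12 to 0.36) in astrocytes, 0.23 (0.05 to 0.45) in granule cells, 0.22 (-0.05 to 0.37) in DCN glutamatergic neurons and 0.11 (-0.12 to 0.32) in DCN inhibitory neurons, the last of these alone within the random lists. Thinning to 1000 UMIs put the DCN inhibitory median at 0.40. Ciart (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251) was 4.73-fold (2.75 to 8.73) higher in oligodendrocytes, with ratios of 1.14 (0.50 to 1.80) in astrocytes and 1.51 (0.40 to 2.63) in granule cells. Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665) was at 1.38 (1.13 to 1.63) in oligodendrocytes and at 0.72 (0.60 to 0.84) in astrocytes, where it stood at 503 CPM in HC and 830 CPM in TN. Also higher in oligodendrocytes were Per2 (1.82, 0.72 to 3.12), Nr1d2 (0.77, 0.43 to 1.11) and Tef (0.61, 0.45 to 0.78). The 4 measured genes that run opposite in phase to the output genes had a median of 0.0056 in oligodendrocytes, so they were not lower as a set. Among them, the activator Clock was at -0.04 (-0.21 to 0.14) and the repressor Nfil3 at -0.67 (-1.85 to 0.51).

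The glucocorticoid list's median was 0.48 (0.23 to 0.64) in granule cells, 0.27 (0.10 to 0.40) in astrocytes, 0.21 (0.03 to 0.55) in DCN glutamatergic neurons and -0.00 (-0.12 to 0.46) in DCN inhibitory neurons, the last pair within the random lists. Oligodendrocyte markers in astrocyte nuclei stood at 1408 CPM in HC and 1967 CPM in TN. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) had ratios of 0.94 (0.70 to 1.19) in oligodendrocytes and 1.39 (0.94 to 1.87) in astrocytes. Sgk1 was at 0.70 (0.61 to 0.79) and 1.08 (0.59 to 1.597), and Pdk4 at 1.16 (0.64 to 1.70) in oligodendrocytes. Plin4, a lipid droplet gene, went from 51.8 to 95.6 CPM there.

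Immediate early genes were not higher in DCN glutamatergic neurons of the TN library, with a median of -0.08 (-0.39 to 0.22) and 5 of 13 higher, and -0.61 when thinned to 1000 UMIs. Fos had 13 UMIs in HC and 6 in TN (-1.07, -2.75 to 0.43), Npas4 15 and 10 (-0.54, -1.85 to 0.71), and Gadd45g, a DNA repair and demethylation factor, was at -0.77 (-1.30 to -0.24). Granule cells had a median of 0.17 (-0.04 to 0.46), with the orphan receptor gene Nr4a2 at 17.4 CPM in HC and 50.4 CPM in TN (1.53, 0.83 to 2.24). Their median was 0.58 with at least 1000 genes per nucleus, a filter that leaves 120 granule nuclei in HC and 48 in TN. Later activity-induced genes had a median of 0.25 (-0.08 to 0.52) in DCN glutamatergic neurons, within the random lists, with Bhlhe40 at 0.82 (0.06 to 1.61).

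Cholesterol synthesis genes had medians of 0.50 (0.30 to 0.61) in astrocytes with 18 of 20 higher, 0.37 (0.14 to 0.45) in DCN glutamatergic neurons with 17 of 20 and 0.25 (0.10 to 0.36) in DCN inhibitory neurons with 17 of 20, but 0.05 (-0.09 to 0.11) in oligodendrocytes. Mvd was at 0.86 (0.07 to 1.71) and Fdft1 at 0.74 (0.19 to 1.31) in astrocytes, Fdps at 0.91 (0.27 to 1.57) in DCN glutamatergic neurons, and Hmgcs1 at 0.54 (0.18 to 0.91) in DCN inhibitory neurons. In DCN glutamatergic nuclei astrocyte markers stood at 113 CPM in HC and 159 CPM in TN (0.49, 0.22 to 0.76), and oligodendrocyte markers at 734 and 984 CPM (0.42, 0.32 to 0.53). Mitochondrially encoded genes were higher, with medians of 0.65 (0.56 to 0.78) in DCN glutamatergic neurons and 0.66 (0.57 to 0.71) in oligodendrocytes, but nuclear oxidative phosphorylation genes were not, at 0.06 (-0.03 to 0.14) and -0.03 (-0.11 to 0.04). Heat shock genes had a median of 0.16 (0.06 to 0.27) in oligodendrocytes, with Hspa1a at 1.69 (0.58 to 2.99) and Hspa5 at -0.96 (-1.15 to -0.77).

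In DCN inhibitory neurons, vesicle release genes had a median of -0.23 (-0.31 to -0.07) with 5 of 25 higher, Unc13c at -1.35 (-2.07 to -0.66) and the calcium sensor gene Syt1 at -0.79 (-1.42 to -0.17), and synaptic plasticity kinases and scaffolds a median of -0.12 (-0.22 to 0.00). Granule markers in these nuclei stood at 126 CPM in TN against 210 CPM in HC. In DCN glutamatergic neurons, potassium and HCN channels had a median of -0.18 (-0.25 to 0.05), with the A-type channel gene Kcnd3 at -0.82 (-1.46 to -0.21) and the pacemaker channel gene Hcn2 at 0.62 (0.18 to 1.07). Thinning to 1000 UMIs put Kcnd3 at 0.29. Ionotropic glutamate receptors had a median of -0.31 (-0.43 to -0.03) in astrocytes, with Grin2b at -0.86 (-1.29 to -0.43), and the median was 0.18 with at least 1000 genes per nucleus. Granule markers in astrocyte nuclei stood at 135 CPM in HC and 78.3 CPM in TN. In oligodendrocytes, GABA and glycine receptors were at -0.41 (-0.60 to -0.09), which became 0.09 with at least 1000 genes, and sodium channels at -0.51 (-1.02 to -0.11). The granule cell genes Gabrd (-1.07) and Gabra6 (-0.98) were among the lower ones there, and granule markers in oligodendrocyte nuclei stood at 254 CPM in HC, 295 in FC and 198 in TN, beside a TN library with fewer granule cells. Purkinje markers there stood at 85.7 CPM in HC and 32.5 CPM in TN, while molecular layer interneuron markers stood at 394 and 494 CPM and DCN inhibitory markers at 173 and 299 CPM. Myelin genes had medians of 0.00 (-0.03 to 0.07) in oligodendrocytes and 0.63 (0.46 to 0.80) in granule nuclei.

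Ranked over single genes, the DCN glutamatergic neurons of TN had more of Gm47283 (1.05, 0.86 to 1.23), Gm45464 (1.51) and Zfp821 (1.22), and less of Lpcat4 (-1.44, -1.94 to -0.96), Rap1gap (-0.82, -1.02 to -0.62, from 331 to 188 CPM), which switches off the small GTPase Rap1, and Slc25a22 (-1.03, -1.51 to -0.56), a mitochondrial glutamate carrier. The DCN inhibitory neurons had more of Ttl (1.64), Sfxn2 (1.5025) and Gm43061 (1.37), and less of Zmym1 (-1.07), Leo1 (-1.42) and Frs3 (-1.42). Granule cells had more of Ptgds (1.35, 1.25 to 1.45), Nr4a2 and AC149090.1 (0.77), and less of Snrpf (-1.51), Hspa5 (-1.11, -1.47 to -0.77) and Ogfod2 (-1.96). Ptgds gave 0.906, 2.40 and 2.25 UMIs per granule nucleus in HC, FC and TN. It was higher in FC and TN than in HC in every class compared, with 1.01, 2.38 and 2.14 per astrocyte nucleus. Oligodendrocyte nuclei gave the most, at 9.59, 12.4 and 14.4. A gain shared by all classes is what free RNA would give, so it is not assigned to granule cells. Astrocytes had more of Gm21860 (1.74), 4932438H23Rik (1.45) and Fkbp5, and less of Snrpf (-1.86), Fabp7 (-1.35) and Ifi27 (-0.99). Oligodendrocytes had more of Tma16 (1.67, 1.46 to 1.88, from 93.2 to 296 CPM), a ribosome assembly factor, Ciart and Zfand4 (1.42), and less of Snrpf (-1.42), Xbp1 (-1.26, -1.64 to -0.90), which drives the unfolded protein response, and Hspa5. Hspa5 (ENSMUSG00000026864) lies on chromosome 2 at 34771970 to 34777547. Gm47283 and Gm21860 lie at the pseudoautosomal end of the Y chromosome, where reads can be shared between copies, and AC149090.1 has no entry in the annotation used.

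Retrieval was compared with conditioning to ask what sets recall apart from learning. Clock genes were higher in TN, with a median of 0.31 (0.16 to 0.50) and 15 of 18 higher in oligodendrocytes, where Nr1d2 was at 0.84 (0.54 to 1.14) and Per3 at 0.78 (0.59 to 0.97). Glucocorticoid-induced genes were not higher in oligodendrocytes, with a median of -0.09 (-0.15 to -0.01), or in astrocytes, at -0.22 (-0.29 to -0.11). With at least 1000 genes per nucleus these were -0.18 and -0.07. In granule cells the list was at -0.02 (-0.25 to 0.15), but at 0.33 with that filter. Fkbp5 differed from that list, at 0.64 (0.44 to 0.84) in oligodendrocytes and 0.68 (0.34 to 1.03) in astrocytes. Immediate early genes of glia were lower in TN, with medians of -0.49 (-0.72 to -0.09) in astrocytes and -0.39 (-0.60 to -0.08) in oligodendrocytes, where Dusp1 was at -0.99 (-1.67 to -0.34). With at least 1000 genes per nucleus the astrocyte median was -1.29. It was -0.17 in astrocyte cluster 3 and -0.55 in cluster 8, and -0.32 and -0.18 in oligodendrocyte clusters 1 and 4.

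In granule cells the clock list's median was 0.26 (0.12 to 0.46) and in astrocytes 0.09 (0.03 to 0.23), which was 0.0038 with at least 1000 genes per nucleus and 0.38 in cluster 8 alone. Gadd45g in astrocytes stood at 195 CPM in HC, 207 in FC and 104 in TN, a ratio of TN over FC of -0.99 (-1.23 to -0.75). The median of immediate early genes in DCN glutamatergic neurons was -0.15 (-0.35 to 0.25), and -0.51 when thinned. Nuclear oxidative phosphorylation genes were lower in TN, at -0.33 (-0.39 to -0.24) with 1 of 31 higher in oligodendrocytes, with Cox8a at -0.66 (-0.85 to -0.47), at -0.27 (-0.33 to -0.15) in astrocytes and at -0.11 (-0.17 to 0.02) in granule cells. The last pair changed sign with at least 1000 genes per nucleus, to 0.07 and 0.15, and granule cells also when thinned, to 0.01. Mitochondrially encoded genes had a median of -0.55 (-0.66 to -0.47) in DCN glutamatergic neurons, with 0 of 12 higher and mt-Cytb at -0.73 (-0.89 to -0.58), but -0.01 (-0.08 to 0.05) in oligodendrocytes. Cholesterol synthesis genes had a median of 0.27 (0.16 to 0.43) in astrocytes with 18 of 20 higher and Msmo1 at 0.60 (0.40 to 0.80). Gfap was lower in TN astrocytes at -0.83 (-1.14 to -0.52), as were Hspa8 at -0.60 (-0.78 to -0.42), in a heat shock list with a median of -0.26 (-0.36 to -0.09), and Rplp0 at -0.88 (-1.31 to -0.47). Cluster 8, whose highest-ranked marker was Gfap, held 174 of the 955 HC astrocytes, 209 of the 1565 FC astrocytes and 115 of the 1199 TN astrocytes. Its share was highest in HC, although Gfap was lower in HC than in FC, so Gfap did not follow this share alone. Monoamine and acetylcholine receptors had a median of 0.53 (0.02 to 0.78) in DCN inhibitory neurons with 4 of 6 higher, among them the nicotinic subunits Chrna4 at 0.94 (-0.06 to 1.99) and Chrnb2 at 0.77 (-0.04 to 1.61). Synaptic plasticity kinases and scaffolds were at 0.11 (-0.04 to 0.16) in astrocytes, which became -0.03 with at least 1000 genes. In oligodendrocytes, sodium channels had a median of -0.87 (-1.24 to -0.54), GABA and glycine receptors -0.59 (-0.91 to -0.31), and vesicle release genes -0.39 (-0.63 to -0.15), which became 0.07 with at least 1000 genes. Granule markers in those nuclei, at 295 CPM in FC and 198 CPM in TN, differed the same way. Molecular layer interneuron markers there, given above, differed little between FC and TN.

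Single genes ranked highest and lowest in TN against FC were Gm47283 (1.01) and Sfmbt1 (-1.69, -2.80 to -0.70) in DCN glutamatergic neurons, Arhgef10l (1.82, 0.93 to 2.79) and Rab7 (-1.59, -2.61 to -0.67) in DCN inhibitory neurons, AC149090.1 (1.11) and Urod (-2.64, -4.56 to -1.20) in granule cells, Gm21860 (3.75, 2.65 to 5.11) and Gadd45g in astrocytes, and AC149090.1 (0.87) and Hspa5 (-0.95, -1.12 to -0.78) in oligodendrocytes. Urod in granule cells was at 2.02 with at least 1000 genes per nucleus. Over the 3 comparisons, 416 list medians had a percentile and 125 lay outside the central 95% of random lists. Lists of unrelated genes would give 20.8. Members of these lists are not independent, so the larger count does not measure an excess over chance.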

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

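The explanations weighed in this part and their tests were chosen after the results were seen, while the list medians and the thinning to 1000 UMIs were planned.

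Some gene lists differed from the home cage library in opposite directions in different cell classes, each median outside the central 95% of matched random lists, and this is what picked them out. All are ratios of FC over HC, and the difference between classes was not tested. Cholesterol synthesis genes were at 0.21 in DCN glutamatergic neurons and 0.18 in granule cells but at -0.14 in oligodendrocytes. Later activity-induced genes were at -0.31 in astrocytes and 0.47 in oligodendrocytes. Vesicle release genes were at -0.11 in DCN inhibitory neurons and -0.13 in granule cells but at 0.24 in oligodendrocytes. Potassium and HCN channels were at -0.20 in astrocytes and 0.32 in oligodendrocytes. The oligodendrocyte value for cholesterol synthesis was 0.02 with at least 1000 genes per nucleus. The astrocyte value for potassium and HCN channels was 0.31 with that filter and 0.07 over members with at least 50 UMIs, so those oppositions do not hold under each setting. Counting intervals include 0 for cholesterol synthesis in granule cells, later activity-induced genes in astrocytes, vesicle release in oligodendrocytes and both values of the channels. With 125 of 416 list medians outside that range, a pair of classes on opposite sides is not rare. Neuronal genes in oligodendrocyte nuclei are also open to free RNA, and granule markers there were at 254 CPM in HC and 295 CPM in FC.

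Glucocorticoid-induced genes such as Sgk1, Pdk4 and Nfkbia were higher in both the FC and the TN library, with the highest medians of the 5 classes in oligodendrocytes. Depth was weighed by thinning to 1000 UMIs, which left the median of FC over HC at 0.59 (0.43 to 0.69). Thinning keeps each gene's expected share within a nucleus and changes mainly how much each nucleus weighs. It could therefore hardly move the median and does not exclude depth. With at least 1000 genes per nucleus that median was 0.93. Free RNA in oligodendrocytes was weighed by the gain of list UMIs per oligodendrocyte nucleus, 5.36 times (4.13 to 7.46) that per granule nucleus. Free RNA that enters droplets evenly would add alike, so this argues against such even entry as the source. Whether entry was even is not settled, though. From HC to FC, oligodendrocyte markers went from 2.01 to 3.10 UMIs per granule nucleus but from 5.31 to 3.80 per DCN inhibitory nucleus. Median depth of DCN inhibitory nuclei also fell, from 3440 to 2561.5 UMIs. Ptgds rose in both classes, from 0.906 to 2.40 per granule nucleus and from 1.67 to 2.55 per DCN inhibitory nucleus. Free RNA that enters unevenly stays open in oligodendrocytes. A shift between oligodendrocyte clusters 1 and 4 was argued against by a lowest median of 0.43 within them. In granule nuclei the gain was 1.91 times (1.37 to 2.4999) in FC and 2.59 times (1.64 to 3.66) in TN what oligodendrocyte RNA would bring. Both intervals lie above 1 but reach under the margin of 2 set for it, and the make-up of free RNA is assumed, so free RNA stays open there as the whole or a part of the gain. A stress hormone response is a candidate explanation in oligodendrocytes, but with 1 library per group the treatment cannot be told apart from handling, transport or differences between animals.

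Clock genes were higher in TN than in HC in oligodendrocytes, astrocytes and granule cells, and than in FC in oligodendrocytes and granule cells, while in astrocytes the median of TN over FC was 0.0038 with at least 1000 genes per nucleus. Oligodendrocyte markers went from 2.01 UMIs per granule nucleus in HC to 2.94 in TN, and from 2.41 to 3.25 per astrocyte nucleus. Whether free RNA adds to the clock medians of those classes was not tested. Genes that peak with the clock's output, such as Ciart and Per3, lay above genes of the opposite phase, such as Clock, by at least 0.41 (0.10 to 0.75, astrocytes, the lowest of 3 classes), as another time of day at collection would give. Both sets were drawn from the clock list after its values were seen, so this gap is not independent support for that explanation. Thinning left the median of TN over HC in oligodendrocytes at 0.55 (0.33 to 0.74). Since thinning keeps each gene's expected share within a nucleus, this does not exclude depth. Glucocorticoid action as the whole cause could not be decided. In oligodendrocytes the clock list was at 0.31 (0.16 to 0.50) in TN over FC while the glucocorticoid list was at -0.09 (-0.15 to -0.01). Fkbp5, a member of the latter list, was higher in TN than in FC, though, in oligodendrocytes and in astrocytes (0.68, 0.34 to 1.03). Retrieval itself as a cause was not tested, since the collection time of each library is not given in the sources used here.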

How the results depend on the processing

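The alternatives of 1 cluster alone, and of the chaperone list without Hspa5, Xbp1, Hsp90b1 and Calr, were chosen after the results were seen, and the others before. No paired analysis was possible because each group has 1 library. Of 1672 values of 152 single genes under 11 settings, 1608 stayed within their counting interval, 57 moved out of it with their direction unchanged or not called, and 7 reversed. Of 4773 list medians (339 under up to 19 settings), 4590 stayed, 167 moved and 16 reversed. Leaving out those 4 genes moved none of 18 chaperone medians out of its interval, and put the one of TN over HC in oligodendrocyte precursors at -0.41. Centring on the median gene and leaving out mitochondrial and the 50 most abundant genes reversed and moved none. TMM scaling moved 2 list medians, and no gene. The glucocorticoid list in oligodendrocytes stayed above 0 under every setting run, from 0.52 to 0.93 in FC over HC. The cause of the changes below was not tested, although the filter of at least 1000 genes leaves far fewer glia and granule cells.

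With at least 1000 genes per nucleus, these FC over HC medians reversed: immediate early genes in astrocytes to -0.0485, potassium and HCN channels in astrocytes to 0.31, ribosomal protein genes in granule cells to -0.066, cholesterol synthesis in oligodendrocytes to 0.0204, and glucocorticoid-induced genes in oligodendrocyte precursors to -0.42. In TN over HC, ionotropic glutamate receptors in astrocytes went to 0.18, and GABA and glycine receptors in oligodendrocytes to 0.0854. In TN over FC, plasticity kinases and scaffolds in astrocytes went to -0.0323, oxidative phosphorylation to 0.0742 in astrocytes and 0.15 in granule cells, astrocyte reactivity in granule cells to 0.49, and vesicle release in oligodendrocytes to 0.0686. Genes that reversed were Fkbp5 in astrocytes (-0.0061), Klk6 (-0.59), Stmn4 (-0.23) and Sgk1 (-0.14) in granule cells and Per3 in oligodendrocytes (-0.41), all in FC over HC, and Urod in granule cells (2.02, TN over FC). In all, 70 list medians and 38 genes moved with this filter. Of the immediate early, glucocorticoid and clock lists in the 5 main classes, those that moved were glucocorticoid-induced genes in astrocytes (0.19 in FC over HC, -0.0677 in TN over FC), in granule cells (0.33 in TN over FC) and in oligodendrocytes (0.93 in FC over HC, 0.76 in TN over HC, -0.18 in TN over FC), immediate early genes in astrocytes (-1.29 in TN over FC) and in granule cells (0.58 in TN over HC, 0.54 in TN over FC), and clock genes in astrocytes (0.0038 in TN over FC).

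Thinning to 1000 UMIs reversed Kcnd3 in DCN glutamatergic neurons (0.29, TN over HC) and, in TN over FC, oxidative phosphorylation in granule cells (0.0085) and potassium and HCN channels in oligodendrocytes (0.0704). It moved 51 list medians and 16 genes, and of the same 3 lists these were clock genes in FC over HC in DCN glutamatergic neurons (-0.23), DCN inhibitory neurons (0.40) and granule cells (-0.26), and in TN over HC in DCN inhibitory neurons (0.40). Immediate early genes also moved, in DCN glutamatergic neurons (-0.61 in TN over HC, -0.51 in TN over FC) and in DCN inhibitory neurons (-0.38 in TN over FC). Members with at least 50 UMIs put potassium and HCN channels at 0.0715 in astrocytes (FC over HC) and 0.0823 in oligodendrocytes (TN over FC), both reversed, and immediate early genes in granule cells at 0.31 (FC over HC). Cluster 8 alone gave, in astrocytes, 0.60 for glucocorticoid-induced and 0.28 for clock genes in FC over HC, 0.22 for immediate early and 0.53 for clock genes in TN over HC, and 0.38 for clock genes in TN over FC. Cluster 1 alone gave 0.52 (FC over HC) and 0.43 (TN over HC) for glucocorticoid-induced and -0.21 for immediate early genes (TN over HC), and cluster 4 alone 0.73 for clock genes (TN over HC).

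Shares of nuclei depended on the filter. In HC, FC and TN, at least 1000 genes gave 15.6%, 24.5% and 18.4% DCN glutamatergic, 18.0%, 26.9% and 23.4% DCN inhibitory, 10.3%, 6.83% and 11.1% astrocytes, 7.21%, 3.70% and 3.03% granule cells and 12.4%, 12.1% and 18.3% oligodendrocytes. No filter gave 3.75%, 4.14% and 4.14%, then 4.41%, 5.06% and 5.37%, 13.9%, 17.7% and 17.4%, and 34.1%, 22.6% and 13.7%, with oligodendrocytes at 36.7% in FC and 46.3% in TN. Without doublet removal, FC had 19.2% astrocytes and 19.0% granule cells, and oligodendrocytes were 25.4%, 32.7% and 42.7%. Removal at 1.6% gave 31.1% and 21.2% granule cells and 27.8% and 35.7% oligodendrocytes in HC and FC. Granule cells stayed highest in HC under each of these. Astrocytes and oligodendrocytes did not stay higher in FC than in HC with at least 1000 genes. DCN glutamatergic nuclei with a core immediate early gene were 0.380%, 1.51% and 1.03% when thinned to 500 UMIs, and 8.59%, 6.01% and 6.92% at 2000, so HC was lowest at 500 and highest at 2000. Depth limits what these genes can show: a DCN glutamatergic total of 13 Fos UMIs in HC leaves a ratio of FC over HC anywhere from -2.96 to 0.21.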

Other observations

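The chaperone list and its tests were chosen after the results were seen, while the glucocorticoid list was planned.

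Genes of protein folding in the endoplasmic reticulum were lower in the TN library. Hspa5, the main chaperone of that compartment, stood at 368 CPM in HC, 260 in FC and 100 in TN in oligodendrocyte precursors, at 207, 205 and 106 CPM in oligodendrocytes and at 122, 135 and 97.53 CPM in astrocytes. In TN over HC, Hsp90b1 was at -0.71 in granule cells and -0.60 in oligodendrocytes, and Calr, which folds glycoproteins, at -0.85 and -0.39. A list of endoplasmic reticulum chaperones and unfolded protein response genes had medians in TN over HC of -0.80 (-1.15 to -0.32) in oligodendrocyte precursors with 3 of 13 higher, -0.74 (-0.95 to -0.20) in microglia with 3 of 13, -0.24 (-0.36 to -0.10) in astrocytes with 6 of 21, -0.23 (-0.40 to -0.11) in oligodendrocytes with 7 of 23, and -0.18 (-0.40 to -0.08) in DCN inhibitory neurons with 7 of 21. In DCN glutamatergic neurons it was -0.08 (-0.29 to 0.04), within the random lists. The list was written after Hspa5, Xbp1, Hsp90b1 and Calr were seen to be low. Without these 4 its medians in TN over HC were -0.36 (-0.54 to -0.12) in granule cells, -0.18 (-0.34 to -0.01) in astrocytes and -0.17 (-0.29 to -0.02) in oligodendrocytes, outside the random lists. They were -0.41 (-0.86 to 0.11) in precursors, -0.46 (-0.82 to 0.19) in microglia and -0.16 (-0.39 to 0.05) in DCN inhibitory neurons, within them. The microglia class also differed in make-up, with border macrophage markers at 648 CPM in HC and 6.48 CPM in TN and oligodendrocyte markers at 5360 and 12545 CPM. In FC over HC the list was at -0.29 (-0.48 to 0.08) in oligodendrocyte precursors with 4 of 14 higher and -0.12 (-0.18 to 0.03) in oligodendrocytes, both outside the random lists, and at -0.13 (-0.27 to -0.02) in granule cells, within them. Without the 4 genes the FC medians of precursors and oligodendrocytes were also within the random lists, at -0.05 and -0.08.

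Free RNA stays open as the source. Each oligodendrocyte precursor nucleus lost 5.74 times (3.86 to 9.00) as many UMIs of this list as each astrocyte nucleus, but this rests in part on the genes that prompted the list. Without these 4 the loss was 4.14 times (1.94 to 9.62), which reaches under the margin of 2 set for it. Nor is free RNA excluded in granule cells, with a loss of 1.88 times (1.33 to 2.91), and in oligodendrocytes, with 1.83 times (1.30 to 2.81), since granule nuclei went from 2.18 UMIs in HC to 1.49 in TN and oligodendrocyte nuclei from 2.81 to 2.14, losing alike. In oligodendrocytes, a general difference in stress genes was argued against by the heat shock list without Hspa5. Its median there in TN over HC was 0.16 (0.09 to 0.30) and so on the other side of 0. Other classes were not tested in this way, and in astrocytes the heat shock list was lower in TN than in FC. Time of day or feeding cannot be told apart from retrieval for the median of -0.44 (-0.61 to -0.25) in granule cells, with 3 of 22 higher, because each group has 1 library and no collection time. Either may underlie the lower chaperone genes.

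The unnamed cluster 7 had a median of -0.40 (-0.57 to -0.11) for the same list in TN over HC, with 5 of 19 higher. The glucocorticoid list had a median of 0.43 (0.03 to 0.78) in oligodendrocyte precursors in TN over HC. Ttr gave 1.16 UMIs per nucleus of cluster 7 in HC.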
